A study of Mus musculus with 40 samples.

How the data were processed

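The study measured polyA RNA in 40 placentas of C57BL6J mice at embryonic day 12.5, with 1 library per placenta sequenced on an Illumina NextSeq instrument. Per the labels' protocols, the mothers ate a wafer every day, from 2 weeks before breeding until the placentas were taken, that carried bisphenol A (BPA) or bisphenol S (BPS) at 200 µg per kg of body weight, or 70% ethanol in the controls (CTL). The treatment and the sex of each placenta were taken from the labels, which gave 10 CTL, 14 BPA and 16 BPS libraries with equal numbers of each sex. Of the 40 titles, 30 are plain numbers and 10 are codes, and the codes hold 4 BPA, 6 BPS and 0 CTL libraries. The labels do not say whether placentas came from separate litters or mothers, so every p-value and interval measures only the spread between these samples.

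The authors deposited a single table of TPM values (length-scaled transcript abundances) for 20468 genes, in which every library sums to 1000000. Per the submitters' processing notes, the reads were processed with cutadapt, HISAT2 and HTSeq against the mm9 build. Versions, gene annotation, the treatment of reads that match several genes and the strand setting were not given in the sources used here. Members of near-identical families, such as the prolactin-like (Prl), pregnancy-specific glycoprotein (Psg), granzyme (Gzm) and haemoglobin genes, and overlapping genes can share reads, so their separate values are uncertain. The annotation at hand was GENCODE M21 on a later build, so it gave the chromosome of a gene by its symbol and no coordinate is printed.

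The table itself carries no depth, but every value was a whole number of reads over a gene length, scaled by 1 factor per library. The factors were solved from ratios between libraries, and 418 rarely seen genes with an annotated exon length set the absolute scale. All 20468 genes came out whole to within 0.01 of a read, with a largest deviation of 8.8e-08, and 1272 of them were at 0 in every library. On simulated tables with the library factors given, the solved length was a divisor of the true length for 1980 of 1980 genes. A library factor also came back from ratios, but the absolute scale was not tested. Of 19861 genes with an annotated exon length, 1013 had exactly that length as recovered, and the log lengths correlated at 0.81. The recovered totals were 66.9 to 112.9 M reads (M, mega) in genes per library, and 1 read on a transcript of 1 kb was worth 0.01887 to 0.02582 TPM. A gene counted at 0 could therefore be present at up to 3 reads, 0.05662 to 0.07745 TPM on 1 kb, which covers counting error only. No pair of libraries held the same values.

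Expression was compared on the log2(TPM + 1) scale, which understates fold changes of weakly expressed genes. A gene was tested if it reached a TPM of 1 in at least 10 libraries, which kept 12738 genes. A linear model with a mean for each treatment and sex was fitted to all libraries with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes, trend and robust). The treatment contrasts gave both sexes equal weight, and p-values were two-sided and adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. A gene past this threshold is described as called. Comparisons were made for both compounds against CTL, for BPA against BPS, within each sex, between the sexes, and for the difference of each treatment effect between the sexes.

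Before the data were examined, 33 gene lists were fixed from general knowledge of the placenta, covering its cell layers, other cell types that a dissected placenta could carry, hormone and nutrient pathways, stress, ribosomes and respiration. Of these, 2 hold sex-linked genes and 1 had under 5 tested members, so 30 were tested with camera in limma at a preset correlation between genes of 0.01, which ranks a list against the other genes. The same test with an estimated correlation and fry, which asks whether the members move on balance in 1 direction, were run beside it. A list score is the mean over its members of log2(TPM + 1) minus the gene's mean over libraries. The ribosomal list was written as a symbol pattern and also took 9 tested S6 kinase genes and the paralogs Rpl22l1, Rpl39l and Rpl3l.

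Genes are named by a rule that was also fixed in advance. All called genes were to be named for each treatment comparison, and with fewer than 10 calls the 10 genes of smallest p, as values only. From each list the rule took up to 4 members that passed over the list alone or, for at most 8 lists, the 2 members of smallest p as values only. For the sexes it took the sex-linked lists and up to 10 other called genes. Genes named outside this rule are marked as chosen after their values were seen.

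The procedure was tested on simulated data with 200 changed genes among 12738, in 20 simulations per comparison. The changed genes were drawn from those with a mean above 1 on the log2(TPM + 1) scale, and each change was added on that scale. For weakly expressed genes such a change is a larger fold in TPM, so the shares below overstate what would be called among them. At a 1.5-fold change it called 77.7% of the changed genes for BPA against CTL, 79% for BPS against CTL and 83% for BPA against BPS. At 1.3-fold the shares were 41.6%, 47.2% and 51.8%, and at 2-fold 97.2%, 96.6% and 98%. The median number of unchanged genes called was 0 in each, with single simulations at up to 38, 2102 and 353. For the BPA comparison, lists were simulated as well: 30 unchanged lists beside a changed list of 15 genes at log2 0.5. The changed list was called in 20 of 20 simulations with either correlation. Of the unchanged lists, camera at the preset correlation called a median of 8.5 and up to 19. With the estimated correlation it called a median of 0 and up to 3.

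The alternatives covered the pseudocount, the filter, median scaling and quantile normalization, an additive model, fits to the compared groups alone, the code-titled libraries, tissue scores as covariates, the variance model, library quality weights (arrayWeights), and leaving out each library in turn. Further fits were chosen after the data were seen, among them limma voom on the recovered reads, normal scores of ranks, a length trend as a covariate, terms for the first 8 libraries by title number, and the removal of 4 doubted libraries (BPA replicate 11, BPA replicate 13, BPS replicate 1 and CTL replicate 8). The code titles form 5 pairs with a shared stem, 1 male and 1 female label each, and the deviations of the pairs from their group means correlated across genes at 0.16 to 0.63. Their mean was 0.49, against 0.13 for the other 40 pairs of code-titled libraries. A fit with the stem as a random block was therefore run as well, with a consensus correlation within stems of 0.845. Quality weights stopped before reaching their convergence tolerance in some simulated and regrouped fits. Unchanged data were also made by shuffling the residuals of the fit 100 times, as whole libraries or for each gene apart. Permutation tests used 100000 resamples, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.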

Results

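Placental RNA from 40 embryos was compared to learn whether BPA or BPS eaten by the mother altered the organ that feeds the embryo and whose hormones and transmitters can reach the developing brain. There were 10 CTL, 14 BPA and 16 BPS placentas, of which 5, 7 and 8 were labelled female. Libraries held 87.3 ± 6.96 M reads in genes in CTL, 94.2 ± 5.35 M in BPA and 95.2 ± 10.8 M in BPS (mean ± SD). The most abundant transcript was Tpbpa, the classical marker of spongiotrophoblast, at 46600 ± 9730 TPM (n = 40). It was followed by Prl3b1, the placental lactogen of giant cells (36900 ± 7960), Tpbpb (20600 ± 5980) and 3 other prolactin family genes, Prl8a9 (17400 ± 3890), Prl7a2 (14100 ± 3980) and Prl2b1 (14000 ± 2840). The placental cathepsin Ctsj reached 12100 ± 2340 TPM and the embryonic haemoglobin Hbb-y 11600 ± 4540. The 10 most abundant genes held 11.7 to 24.7% of all TPM in a library.

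Some libraries stood apart from their groups. The library labelled BPA replicate 11, female, held 80.2 TPM over the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, against 92.6 ± 20.9 (62 to 127) in the 20 libraries labelled male and at most 0.795 in the other libraries labelled female. In BPA replicate 13, 292 genes of chromosome 19 stood at a median log2 difference of 0.54 from the other libraries. BPS replicate 1 had the fewest reads in genes, 66.9 M, and CTL replicate 8 had the highest score of maternal decidua markers, 1.88 against 0.67 in the next CTL library. Across the 40 libraries the first principal component, 43.2% of the variance, followed the slope of expression on gene length within a library (r = -0.93, permutation p = 1e-05, the smallest possible, adjusted p = 2e-05 over 2 relations). On this axis BPS replicate 1 lay farthest out (component 98.5, slope -0.507), followed by CTL replicate 1 (54.6 and -0.273). Without the 2 farthest libraries r was -0.84, and it was -0.94 among number-titled and -0.85 among code-titled libraries.

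**Figure D1:**
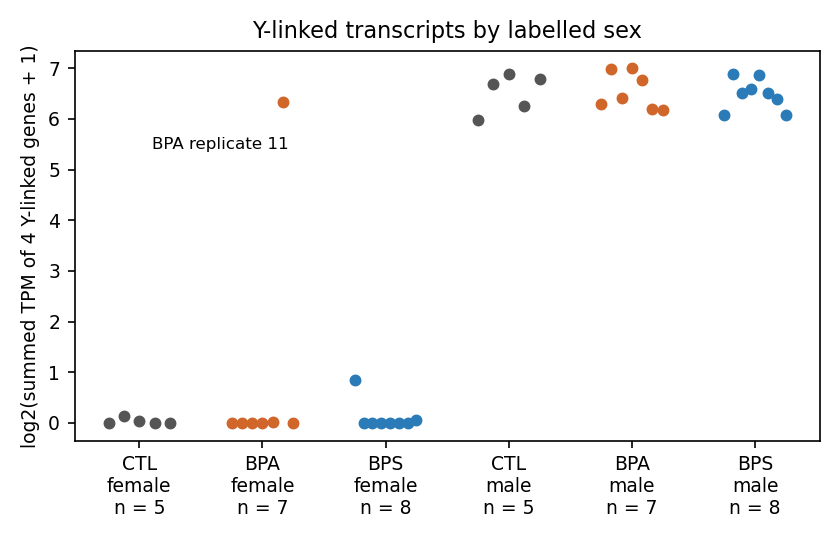
Y-linked transcripts per library: summed TPM of Ddx3y, Uty, Kdm5d and Eif2s3y by treatment group and labelled sex. The library labelled BPA replicate 11, female, lay at 80.2 TPM, within the 62 to 127 of the libraries labelled male.

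**Figure D2:**
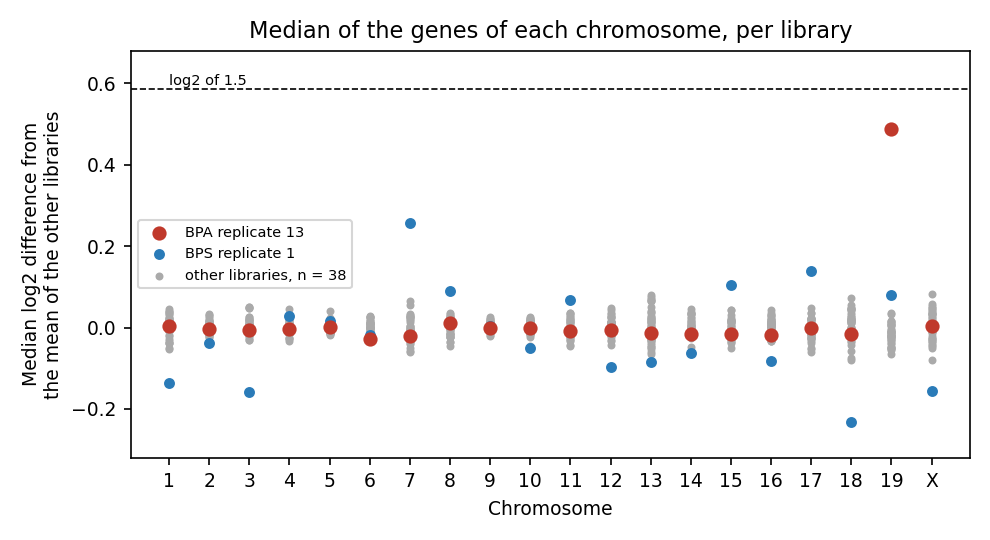
Median log2 difference of tested genes from the other libraries, by chromosome and library. Chromosome 19 lay at 0.49 over all 435 of its tested genes in BPA replicate 13.

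Whether male and female placentas differed was asked across the 3 treatments. Males carried the Y-linked transcripts, and 4 X-linked genes were lower in males than in females. Of the Y-linked genes, the RNA helicase gene Ddx3y rose to 50.3 ± 12.7 TPM in males (log2 5.38, SE 0.27, adjusted p = 6.79e-18) and Eif2s3y, a translation initiation factor subunit, to 25.6 ± 9.30 (log2 4.36, SE 0.28, adjusted p = 1.15e-14). The histone demethylase family genes Uty (log2 3.29, SE 0.18, adjusted p = 6.4e-17) and Kdm5d (log2 2.69, SE 0.17, adjusted p = 6.81e-15) rose as well. Each of the 4 was above the female median in 20 of 20 males. The libraries labelled female include BPA replicate 11, with Ddx3y at 34.9 TPM against 0.012 ± 0.032 in the other 19, which lowers these log2 values. Number-titled libraries alone, without that library, gave log2 5.73 for Ddx3y, 4.64 for Eif2s3y, 3.5 for Uty and 2.93 for Kdm5d. The X-linked prolyl isomerase gene Pin4 was lower in males, 58.6 ± 8.39 against 88.3 ± 14.9 TPM (log2 -0.58, SE 0.07, adjusted p = 9.95e-07, lower in 20 of 20 males). The X-linked genes Utp14a, a ribosome assembly factor (log2 -0.37, lower in 20), Rps4x, a ribosomal protein of the small subunit (log2 -0.36, 1132 ± 180 TPM in females and 875 ± 125 in males, lower in 18), and Pbdc1 (log2 -0.31, lower in 19) had adjusted p = 0.00687. So did 3 autosomal genes: the acetyltransferase gene Naa11 (log2 0.51, higher in 18 of 20 males), Pdxp, a pyridoxal phosphatase (log2 -0.32, lower in 20), and Acat1, a mitochondrial thiolase (log2 -0.30, lower in 19).

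In all, limma called 11 genes between the sexes, 5 higher and 6 lower in males, with 333 at an unadjusted p under 0.05 where 637 were expected by chance, against 15 called by voom and 7 by normal scores. The 4 tested genes of the list of X genes fixed in advance were not among these 11: Kdm5c at log2 -0.40 (adjusted p = 0.379, lower in 17 of 20 males), Eif2s3x at -0.52 (0.505, lower in 19), Kdm6a at -0.23 (0.999, lower in 17) and Ddx3x at -0.04 (0.999, lower in 11). Their calls depended on the libraries and settings. Without BPS replicate 1 both Kdm5c (adjusted p = 0.00694) and Eif2s3x (0.00129) were called, as they were with library quality weights (0.00201 and 0.000358) and with the slope on gene length as a covariate (8.08e-07 and 0.000611), which also called Kdm6a (0.0126). Kdm5c alone was called with median scaling (0.00426), quantile normalization (0.000651), the title stem as a random block (0.0233), voom (0.0417) and a term for the first 8 libraries by title number (0.0106). In the remaining alternatives with all or number-titled libraries, Kdm5c and Eif2s3x stood at adjusted p of up to 1. Ddx3x turned to 0.001 without BPA replicate 2 and 0.017 without CTL replicate 1. Number-titled libraries alone gave 6 calls, the 4 Y-linked genes, Pin4 (log2 -0.58, adjusted p = 6.63e-05) and Naa11 (log2 0.52, adjusted p = 0.0213). In them Pbdc1 (0.104), Rps4x (0.138), Utp14a (0.218), Pdxp (0.277) and Acat1 (0.461) lost theirs. The 10 code-titled libraries, which include BPA replicate 11, gave 0 calls with 724 genes at an unadjusted p under 0.05, and Ddx3y there stood at log2 4.00 (adjusted p = 0.866). The count was 23 without BPS replicate 1, 22 without BPA replicates 11 and 13, BPS replicate 1 and CTL replicate 8 (with Kdm5c at 0.0192 and Eif2s3x at 0.000557), and 67 (8 higher, 59 lower) with the shared title stem as a random block.

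Placentas exposed to BPA were compared with CTL to find genes that followed the compound. Preb, which takes part in export from the endoplasmic reticulum, stood at 44.0 ± 2.38 TPM in BPA and 39.5 ± 2.82 in CTL (log2 0.15, 95% interval 0.06 to 0.25) and was above the CTL median in 14 of 14 BPA libraries. Fdft1, the squalene synthase of cholesterol synthesis, was at log2 0.18 (13 of 14 above the CTL median), the SLC26 family transporter gene Slc26a10 at 0.22 (13), the peptidase gene Apeh at 0.18 (12), the centrosome gene Cep19 at 0.14 (13), Zfp358 at 0.22 (11) and the Wnt pathway gene Frat1 at 0.18 (13). The ribosomal protein paralog Rpl22l1 stood at 664 ± 130 TPM against 830 ± 154 (log2 -0.33, SE 0.11, above the CTL median in 2 of 14), H2-DMb1, which serves peptide loading of class II molecules, at log2 -0.26 (2) and the X-linked Zcchc13 at -0.22 (1). These 10 genes had the smallest p-values and none was called: each had adjusted p = 0.94. They were picked by p in these same libraries, so their counts above the CTL median give no independent support. Frat1 lies on chromosome 19 and was at 0.15 without BPA replicate 13.

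Limma called 0 of 12738 genes between BPA and CTL, with 178 at an unadjusted p under 0.05 (114 higher and 64 lower, 637 expected), and voom and normal scores also called 0. On the log2(TPM + 1) scale the 95% interval lay within 2-fold for 99.2% of genes and within 1.5-fold for 93.6%, which is a looser bound in TPM for weakly expressed genes. Number-titled libraries alone called 0 genes, with Preb at log2 0.14, Slc26a10 at 0.18, Fdft1 at 0.14 and Rpl22l1 at -0.22 (adjusted p = 0.995 for each).

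Among the gene lists, genes of steroid hormone synthesis and metabolism stood lower in BPA placentas than in CTL. Of 14 tested members 10 were lower (mean log2 -0.10), and the list score was under the CTL median in 11 of 14 BPA libraries. Camera called the list at adjusted p = 0.000556 at the preset correlation and 0.0174 with an estimated correlation, and at 0.00304 with the number-titled libraries alone. For this list the estimated correlation was 0.012, close to the preset 0.01, so it was hardly a separate check. Fry did not call the list (adjusted p = 0.798). No member passed over the list alone: Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, stood at 129 ± 29.5 against 165 ± 69.1 TPM (log2 -0.29, SE 0.16, above the CTL median in 2 of 14) and Sult1e1, the estrogen sulfotransferase, at 14.7 ± 3.57 against 19.2 ± 5.48 (log2 -0.35, SE 0.18, in 1 of 14). With the slope on gene length as a covariate the adjusted p of the list was 0.0525.

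Lists of maternal and immune cell markers were called between BPA and CTL at the preset correlation, and each lost its call with the estimated correlation. Of the uterine natural killer cell markers, 0 of 11 were higher (mean log2 -0.33, adjusted p = 2.42e-10, and adjusted p = 0.186 with an estimated correlation). The receptors Klrd1 and Klrg1 stood at log2 -0.44 and -0.36 (above the CTL median in 4 and 6 of 14). Of the maternal decidua markers 10 of 12 were lower (mean log2 -0.24, adjusted p = 2.3e-06, and adjusted p = 0.286 with an estimated correlation). Much of that value rests on CTL replicate 8, which held the highest decidua score, Cxcl14 and Prl8a2 of its group: without it 7 of 12 markers were lower (mean log2 -0.047, adjusted p = 0.0393). The chemokine Cxcl14 stood at -0.74 (SE 0.46, above the CTL median in 5 of 14), and at -0.26 (SE 0.37) without CTL replicate 8. The decidual prolactin Prl8a2 stood at -0.58 (SE 0.37, 1084 ± 545 against 2059 ± 2559 TPM) though 8 of 14 BPA libraries lay above the CTL median. Without CTL replicate 8 it was at -0.28 (SE 0.34), with 1276 ± 683 TPM in CTL. The natural killer markers had a mean of -0.234 without this library (adjusted p = 3.84e-08). By library, 8 of 14 BPA libraries lay under the CTL median of the natural killer score and 7 of 14 under that of the decidua score. The group means differed by -0.33 (permutation p = 0.229) and -0.24 (permutation p = 0.355), with adjusted p = 0.355 for both. Of the neutrophil markers 5 of 5 were lower (mean log2 -0.28, score lower in 12 of 14 libraries, adjusted p = 1.09e-05, and adjusted p = 0.0589 with an estimated correlation). The calprotectin genes S100a8 (SE 0.24) and S100a9 (SE 0.33) stood at -0.52, and at -0.54 and -0.17 in number-titled libraries alone.

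**Figure D3:**
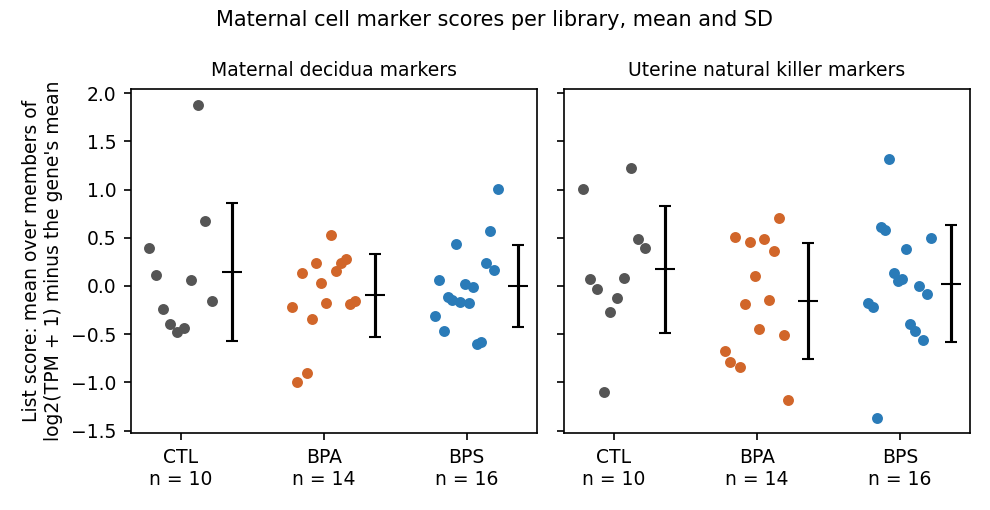
Scores of maternal decidua and uterine natural killer cell markers per library, as mean log2 difference from the average, by treatment group. The natural killer score was 0.174 ± 0.66 in CTL, -0.152 ± 0.603 in BPA and 0.025 ± 0.606 in BPS (mean ± SD).

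Trophoblast and housekeeping lists stood apart by small amounts between BPA and CTL. Cytosolic ribosomal proteins had 61 of 93 members lower (mean log2 -0.05, score lower in 9 of 14 libraries, adjusted p = 5.16e-15, and adjusted p = 0.4 with an estimated correlation), with the paralog Rpl39l at -0.43. Spongiotrophoblast and glycogen cell markers had 17 of 30 lower (mean log2 -0.042, score lower in 6 of 14 libraries, adjusted p = 0.000165, and adjusted p = 0.481 with an estimated correlation). Prl7b1 stood at -0.36 and the cathepsin Cts7 at -0.32, and at -0.24 and -0.20 in number-titled libraries alone. That call ended without BPA replicate 4 (0.743) or BPA replicate 1 (0.065). Giant cell markers had 9 of 13 lower (mean log2 -0.043, score lower in 5 of 14 libraries, adjusted p = 0.00837, and adjusted p = 0.481 with an estimated correlation). They lost the call without BPA replicate 4 (0.433), CTL replicate 2 (0.369), CTL replicate 1 (0.238) or CTL replicate 10 (0.0641), and with median scaling (0.125). Interferon stimulated genes had 7 of 12 lower (mean log2 -0.052, 10 of 14 libraries, adjusted p = 0.000918, and adjusted p = 0.481 with an estimated correlation). Ifit3 was at -0.24 and Isg15 at -0.18, and the list stood at 0.0516 without CTL replicate 8. Oxidative phosphorylation subunits were called as lower with 44 of 83 members lower, a mean of 0.002 and a median of -0.003 (score lower in 7 of 14 libraries, adjusted p = 0.000388, and adjusted p = 0.862 with an estimated correlation). Ndufs3 of respiratory complex I stood at 0.17 and Cox6c of complex IV at -0.18 (-0.11 in number-titled libraries alone). The direction of the list turned without CTL replicate 1 (adjusted p = 0.741), and the call also ended without BPA replicate 8 (0.101), CTL replicate 2 (0.075) or BPA replicate 6 (0.06). DNA methylation and histone deacetylation genes were higher in 14 of 14 (mean log2 0.13, score higher in 9 of 14 libraries, adjusted p = 0.0411, and adjusted p = 0.862 with an estimated correlation). This call ended without any 1 of 11 libraries, at most at 0.132 without CTL replicate 8. The median of all tested genes was itself higher in BPA than in CTL, at log2 0.064.

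In all, camera at the preset correlation called 10 of 30 lists between BPA and CTL, 1 higher and 9 lower, against 1 with the estimated correlation and 0 with fry. With median scaling it called 13, 5 higher and 8 lower. In simulated data the preset correlation called a median of 8.5 of 30 unchanged lists, and the estimated correlation a median of 0 and up to 3. Only the steroid list was also called with the estimated correlation, which is above that median but within the highest count that unchanged lists gave.

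Placentas exposed to BPS were compared with CTL in the same way. Some members of the trophoblast progenitor and endoplasmic reticulum stress lists passed when tested within their lists, without adjustment over the lists searched. Camera at the preset correlation did not call these lists (adjusted p = 0.691 and 0.428). Cdx2, a transcription factor of trophoblast stem cells, stood at 44.3 ± 8.24 TPM in CTL and 53.2 ± 6.45 in BPS (log2 0.27, SE 0.09, above the CTL median in 16 of 16 libraries). Tfap2c, another trophoblast regulator, stood at log2 0.22 (15 of 16). Id2, a repressor of helix-loop-helix factors, stood at -0.16 (above the CTL median in 1 of 16). These 3 of 11 progenitor genes had adjusted p = 0.0337 over the list alone, and 0.512 for Cdx2 and 0.529 for Tfap2c and Id2 over all genes. Creld2, a gene induced by stress of the endoplasmic reticulum, stood at log2 0.31 (adjusted p = 0.0151 over its list of 16, 0.392 over all genes, 16 of 16). In number-titled libraries alone, the 4 stood at log2 0.25, 0.17, -0.18 and 0.22, with adjusted p = 1 over all genes.

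The 10 genes of smallest p between BPS and CTL lay to 1 side of the CTL median in at least 15 of 16 BPS libraries but were not called in the main model. They were picked by p in these same libraries, so such counts give no independent support. Preb again stood higher, 45.7 ± 2.77 against 39.5 ± 2.82 TPM (log2 0.21, SE 0.04, adjusted p = 0.178, 16 of 16 above the CTL median), as did Slc26a10 (log2 0.34, 95% interval 0.19 to 0.48, adjusted p = 0.178, 15 of 16) and Rgl3, an exchange factor for Ral GTPases (log2 0.39, SE 0.08, adjusted p = 0.178, 16 of 16). Snai1, a repressor that drives epithelial-to-mesenchymal transition, stood at 65.2 ± 4.08 against 52.9 ± 6.51 TPM (log2 0.30, SE 0.07, adjusted p = 0.259, 16 of 16). The carboxypeptidase-like gene Cpxm1 (log2 0.46), Ssbp4 (0.33) and the dynein light chain gene Dynlt1b (0.42) had adjusted p of 0.362, 0.362 and 0.392 and lay above the CTL median in 16, 16 and 15 of 16. The ubiquitin-conjugating enzyme Ube2b (log2 -0.28, adjusted p = 0.259), the exosome cofactor C1d (-0.36, 0.362) and the tetraspanin Cd9 (-0.22, 0.362, 751 ± 66.9 against 871 ± 55.5 TPM) lay above the CTL median in 0 of 16. In number-titled libraries alone Slc26a10 stood at 0.32, Preb at 0.19, Rgl3 at 0.34, Snai1 at 0.33, Ube2b at -0.22 and Cd9 at -0.20, with adjusted p = 1.

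Limma called 0 of 12738 genes between BPS and CTL, with 944 at an unadjusted p under 0.05 (621 higher and 323 lower, 637 expected), and voom and normal scores called 0. Library quality weights raised the count to 91 (0 with weights and number-titled libraries alone). Median scaling raised it to 3, quantile normalization to 3 and the slope on gene length as a covariate to 28. Of the genes of smallest p named above, the slope fit, chosen after the results were seen, called Preb (adjusted p = 0.00798), Slc26a10 and Rgl3 (0.0242 each). It also called Snai1, Ube2b and Cd9 (0.0362 each), but not the rest of them. Median scaling called Rgl3 (0.00395). Number-titled libraries alone gave 0 with 251 at an unadjusted p under 0.05. On the log2(TPM + 1) scale the 95% interval lay within 2-fold for 99.4% of genes and within 1.5-fold for 94.6%.

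**Figure D4:**
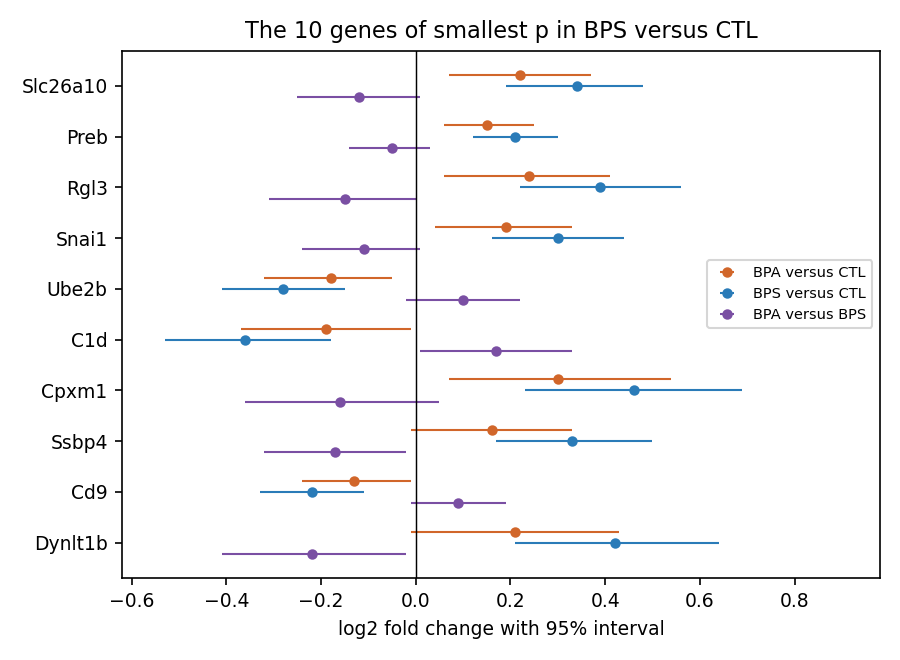
Log2 fold changes with 95% intervals of the 10 genes of smallest p between BPS and CTL, shown for the 3 comparisons. Slc26a10 lay at 0.34 in BPS and 0.22 in BPA against CTL.

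In the gene lists, steroid hormone genes were lower in BPS as well, with 10 of 14 members lower (mean log2 -0.15, score lower in 14 of 16 libraries). Camera gave adjusted p = 0.0134 at the preset correlation and adjusted p = 0.0942 with an estimated correlation. Star, which carries cholesterol into mitochondria, stood at 75.4 ± 24.6 against 106 ± 27.7 TPM (log2 -0.50, SE 0.17, adjusted p = 0.0879 over the list alone, above the CTL median in 2 of 16) and Sult1e1 at -0.42 (adjusted p = 0.148 over the list alone, 4 of 16). The call ended without CTL replicate 1 (0.217), CTL replicate 2 (0.163) or BPS replicate 5 (0.0612), with median scaling (0.117) and with number-titled libraries alone (0.0646).

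Smooth muscle markers were higher in 8 of 8 (mean log2 0.24, score higher in 15 of 16 libraries, adjusted p = 0.0258, and adjusted p = 0.984 with an estimated correlation). Smoothelin (Smtn) stood at 0.33 (adjusted p = 0.0692 over the list alone, 14 of 16) and smooth muscle actin (Acta2) at 0.38 (0.159, 13 of 16). Their call ended without CTL replicate 2 (0.113), CTL replicate 1 (0.103), BPS replicate 1 (0.0781), CTL replicate 10 (0.0686) or BPS replicate 15 (0.0531). Nutrient transporters were higher in 17 of 18 (mean log2 0.12, 12 of 16 libraries, adjusted p = 0.0457, and adjusted p = 0.984 with an estimated correlation). The amino acid transporter chain Slc3a2 stood at 0.23 and the glucose transporter Slc2a1 at 0.27. The median of all tested genes was itself higher in BPS than in CTL, at log2 0.035. Giant cell markers had 9 of 13 lower (mean log2 -0.18, 9 of 16 libraries, adjusted p = 0.00815, and adjusted p = 0.984 with an estimated correlation). The proliferin genes Prl2c2 and Prl2c5 stood at -0.68 and -0.30, and the call ended without CTL replicate 2 (0.186), CTL replicate 1 (0.168) or BPS replicate 5 (0.0612). Natural killer cell markers had 11 of 11 lower (mean log2 -0.15, 10 of 16 libraries, adjusted p = 0.0438, and adjusted p = 0.984 with an estimated correlation). Klrd1 stood at -0.47 and Klrg1 at -0.21, and without CTL replicate 8 the mean was -0.057 with 8 of 11 lower (adjusted p = 0.207). Ribosomal proteins had 54 of 93 lower (mean log2 -0.022, 9 of 16 libraries, adjusted p = 0.00815, and adjusted p = 0.984 with an estimated correlation), with Rpl22l1 at -0.36 and Rps7 at -0.20. The calls of nutrient transporters, natural killer markers and ribosomal proteins ended without any 1 of 17, 13 and 7 libraries, at most at 0.235, 0.393 and 0.879, each without CTL replicate 1. In number-titled libraries alone Acta2 stood at 0.17, Smtn at 0.24, Slc3a2 at 0.10, Slc2a1 at 0.16, Prl2c2 at -0.42, Prl2c5 at -0.14, Klrg1 at -0.05 and Rpl22l1 at -0.26.

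Camera thus called 6 of 30 lists between BPS and CTL, 2 higher and 4 lower, against 0 with the estimated correlation and 0 with fry. With median scaling it called 3, all higher: the 4 lower lists lost their calls, with giant cell markers, steroid hormone genes and ribosomal proteins at 0.117 and natural killer markers at 0.209. The count was 0 without CTL replicate 1 or CTL replicate 2, 1 without BPS replicate 5, 3 without BPS replicate 7, 14 or 15, and 10 without BPS replicate 1 or CTL replicate 5. Number-titled libraries alone gave 3, and of the 6 lists kept the ribosomal proteins (adjusted p = 0.018), while giant cell markers (0.514), natural killer markers (0.776), smooth muscle (0.316) and nutrient transporters (0.338) lost the call.

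BPA and BPS, which differ in the group that joins their phenol rings, an isopropylidene bridge in BPA and a sulfonyl bridge in BPS, were given at the same dose and compared with each other. Cdx2 was lower under BPA than under BPS, 43.2 ± 8.06 against 53.2 ± 6.45 TPM (log2 -0.31, 95% interval -0.48 to -0.14, adjusted p = 0.00933 over the progenitor list alone, 1 over all genes), and 3 of 14 BPA libraries lay above the BPS median. It stood at -0.35 in number-titled and -0.17 in code-titled libraries. Ceacam15, of the carcinoembryonic antigen family, stood at log2 -0.58 (95% interval -0.94 to -0.21, above the BPS median in 2 of 14), Gsg1l at -0.41 (1), the peptide transporter gene Tap2 at -0.28 (3), the signalling adaptor Hcls1 at -0.27 (5), Proser2 at -0.25 (3), the palmitoyltransferase gene Zdhhc14 at -0.22 (1), and Ankrd37, a target of hypoxia signalling, at -0.28 (3). The glycosyltransferase gene Gcnt1 stood at 0.36 (13 of 14) and 1110059E24Rik at 0.18 (11), both on chromosome 19, at 0.34 and 0.16 without BPA replicate 13. In number-titled and code-titled libraries these genes kept their signs but differed in size, as for Ceacam15 (-0.78 and -0.14), Gsg1l (-0.50 and -0.21), Ankrd37 (-0.36 and -0.16), Proser2 (-0.31 and -0.12) and Zdhhc14 (-0.25 and -0.11). The adjusted p of these genes was 1 over all genes. They were picked by p in these same libraries, so the counts and the kept signs give no independent support.

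Limma called 0 of 12738 genes between BPA and BPS, with 163 at an unadjusted p under 0.05 (65 higher and 98 lower in BPA, 637 expected), and voom and normal scores called 0. On the log2(TPM + 1) scale the 95% interval of the difference lay within 2-fold for 99.6% of genes and within 1.5-fold for 96.3%. The median interval reached 0.201 to either side in log2, which does not show that the compounds acted alike. It describes the spread between these placentas, and can be too narrow for a treatment effect if placentas shared a litter. Number-titled libraries alone called 0 (172 at an unadjusted p under 0.05) and code-titled libraries alone 0 (95).

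Gene lists were compared between BPA and BPS as well, and each of those called at the preset correlation lost its call with the estimated correlation. Spongiotrophoblast and glycogen cell markers had 25 of 30 lower under BPA (mean log2 -0.072, adjusted p = 0.00039, and adjusted p = 0.88 with an estimated correlation). Ascl2, a regulator of this lineage, stood at -0.22 and Cts7 at -0.21, and the score was lower in 7 of 14 libraries. The call ended without BPA replicate 4 (0.843) or BPA replicate 1 (0.132). Natural killer markers had 9 of 11 lower (mean log2 -0.18, 8 of 14 libraries, adjusted p = 0.00309, and adjusted p = 0.88 with an estimated correlation). The granzymes Gzmg and Gzmc stood at -0.30 and -0.29. This list lost its call without BPA replicate 4 (0.19), BPA replicate 14 (0.154), BPA replicate 1 (0.113), BPS replicate 6 (0.0861) or BPS replicate 1 (0.0856). Erythroid markers were higher in 8 of 9 (mean log2 0.28, 8 of 14 libraries, adjusted p = 0.0219, and adjusted p = 0.88 with an estimated correlation). Glycophorin (Gypa) stood at 0.56 and the anion exchanger Slc4a1 at 0.38, and the call ended without any 1 of 10 libraries, at most at 0.245 without BPA replicate 2. Serotonin, dopamine and tryptophan genes, a list of enzymes, transporters and receptors, had 9 of 16 lower (mean log2 -0.045, 10 of 14 libraries, adjusted p = 0.0421, and adjusted p = 0.88 with an estimated correlation). The tryptophan-degrading enzyme Ido1 stood at -0.35 and tyrosine hydroxylase (Th) at -0.13, both weakly expressed (1.84 and 1.37 TPM in BPA). That call ended without any 1 of 13 libraries, at most at 0.152 without BPA replicate 1. In number-titled and code-titled libraries Th stood at -0.25 and 0.08, Ido1 at -0.53 and -0.08, Gypa at 0.68 and 0.17, Slc4a1 at 0.41 and 0.17, Gzmg at -0.43 and -0.09, Gzmc at -0.43 and 0.00, Ascl2 at -0.16 and -0.30 and Cts7 at -0.17 and -0.38.

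The other 5 lists called between the compounds had small means. Trophoblast progenitor markers had 6 of 11 lower (mean log2 -0.04, score lower in 10 of 14 libraries), decidua markers 10 of 12 (-0.092, 7 of 14 libraries, Cxcl14 at -0.37 and Cryab at -0.19) and hypoxia genes 11 of 16 (-0.042, 10 of 14 libraries, with Hif1a at 0.18), each at adjusted p = 0.0421, and adjusted p = 0.88 with an estimated correlation. These 3 calls ended without any 1 of 9, 13 and 11 libraries, at most at 0.209, 0.513 and 0.279, each without BPA replicate 4. Ribosomal proteins had 63 of 93 lower (mean log2 -0.028, 8 of 14 libraries, adjusted p = 0.000752, and adjusted p = 0.88 with an estimated correlation). Among them Rpl3l stood at -0.16 and the kinase gene Rps6ka6 at 0.21. Oxidative phosphorylation subunits had 57 of 83 lower (mean log2 -0.024, 7 of 14 libraries, adjusted p = 0.00309, and adjusted p = 0.88 with an estimated correlation), with the hypoxia-linked Cox4i2 at -0.30 and Ndufa4l2 at -0.23. Without BPS replicate 1 both turned direction (0.154 and 0.0916), the ribosomal call ended without BPA replicate 8 (0.0564), and the subunits lost theirs without any 1 of 9 libraries, at most at 0.196 without BPA replicate 8. In number-titled and code-titled libraries Cxcl14 stood at -0.20 and -0.61, Cryab at -0.22 and -0.02, Rpl3l at -0.25 and 0.00, Rps6ka6 at 0.26 and 0.05 and Ndufa4l2 at -0.31 and -0.14. Camera called 9 of 30 lists in all, 1 higher and 8 lower, against 0 with the estimated correlation and 0 with fry. With median scaling it called 6, 1 higher and 5 lower, and decidua markers (0.116), hypoxia genes (0.116) and serotonin and dopamine genes (0.13) lost the call. The count was 2 without BPA replicate 1, 4 without BPA replicate 2 and 5 without BPS replicate 5 or 10.

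Within each sex the treatments were compared to see whether male and female placentas responded apart. Limma called 0 genes in females for BPA against CTL, BPS against CTL and BPA against BPS (64, 424 and 43 at an unadjusted p under 0.05), and 0 in males (396, 900 and 269). Voom and normal scores called 0 in each. The tests of the difference between the sexes called 0 genes for BPA (102 at an unadjusted p under 0.05, smallest adjusted p = 0.794) and 0 for BPS (80, 0.647), again with 0 by voom and normal scores. The BPA females include BPA replicate 11, labelled female but with Y-linked transcripts at male level. These counts stayed at 0 without that library. In males the median gene stood at log2 0.146 under BPA and 0.116 under BPS against CTL, and in females at -0.018 and -0.048. In simulated data for BPS against CTL in males, 50.8% of genes changed by 1.5-fold were called.

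Whether the 2 compounds moved the same genes was tested against what shared controls give. The log2 changes of BPA and BPS against CTL correlated at r = 0.711 over 12738 genes and had the same sign in 76.2%. Unchanged groups simulated against shared controls gave a mean r of 0.594 (SD 0.248), at least as high as observed in 43 of 100 simulations, and a covariance of 0.0097 against 0.0098 observed. With the controls divided, 5 for each compound, r averaged 0.115 (-0.358 to 0.498 over 100 splits). It was 0.456 with number-titled libraries alone. Some named genes, picked here after their values were seen, had the same sign against these shared controls under BPA and BPS: Preb (log2 0.15 and 0.21), Slc26a10 (0.22 and 0.34), Snai1 (0.19 and 0.30) and Rpl22l1 (-0.33 and -0.36). Others stood apart, such as Cdx2 (-0.04 and 0.27), Star (-0.11 and -0.50), Gcnt1 (-0.02 and -0.38) and Ceacam15 (-0.06 and 0.51).

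Hormone receptors and their targets, the textbook route of bisphenol action, were examined as 2 lists. The 12 tested nuclear and estrogen receptor genes were not called for BPA against CTL (mean log2 0.03, adjusted p = 0.758, 8 of 12 higher), BPS against CTL (0.033, 0.906, 8 higher) or BPA against BPS (-0.002, 0.396, 6 higher). The 12 estrogen responsive genes were not called either (means 0.072, 0.039 and 0.033, adjusted p = 0.791, 0.906 and 0.5, with 10, 7 and 4 members higher). The estrogen receptor gene Esr1, picked after its values were seen, stood at 2.12 ± 1.96 TPM in CTL, 1.61 ± 0.739 in BPA and 1.73 ± 0.680 in BPS.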

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

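The tests of explanations for these results were chosen only after the results were seen, apart from the unweighted comparison of number-titled with all libraries for the genes called with quality weights. Groups of up to 10 libraries were searched for a single library far from the others, measured as its gap to the nearest library divided by the range of the group. Such a library was found in 18 of 126 groups of values, where chance gives about 1 in 20 groups, or 6.3 here.

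In CTL, replicate 8 was the highest library for the decidual genes Cxcl14 (0.57, at 7.13 against 3.86 in the next on the log2(TPM + 1) scale), Prl8a2 (0.478, 13.15 against 11.32) and Hoxa10 (0.528, 6.27 against 4.67), and for the score of maternal decidua markers (0.515, 1.88 against 0.67). CTL replicate 1 was the lowest for Apeh (0.543, 4.34 against 4.53), for Hif1a (0.524, 6.36 against 6.69) and, among CTL males, for Uty (0.807, 2.58 against 3.46). CTL replicate 9 was the lowest for Frat1 (0.553, 0.87 against 1.13), and CTL replicate 10 the highest for the cathepsin Cts7 (0.538, 2.81 against 1.76). Among CTL females, replicate 3 was the highest for Kdm5d (1, at 0.01 against 0) and Eif2s3y (0.75, 0.08 against 0.02). Among BPS females, replicate 1 was the highest for Ddx3y (0.789, 0.19 against 0.04), Kdm5d (1, 0.05 against 0) and Eif2s3y (1, 0.69 against 0).

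Among BPA females, the library labelled replicate 11 was far above the others for Ddx3y (0.998, 5.17 against 0.01), Uty (1, 3.2 against 0), Kdm5d (1, 2.7 against 0) and Eif2s3y (0.996, 5.03 against 0.02). A small share of male RNA in a female library is argued against by the summed Y-linked level, 129% of the lowest library labelled male. A swap with a library labelled male is argued against as well, since 0 of them lacked these transcripts. A male placenta under a female label remains a candidate explanation, at 86.6% of the male mean, within the 66.9 to 137% of the males, and so does a swap with a sample outside the study, which was not tested. No biological explanation was tested.

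In BPA replicate 13, genes of chromosome 19 stood apart, a pattern found in a scan of 20 chromosomes in 40 libraries: of 292 genes with a mean TPM of at least 10, 99% lay above the mean of the other libraries, against 47.2 to 58.1% on other chromosomes, with quartiles of 0.44 and 0.67 in log2 and a median fold of 1.45. Another mix of cell types, which has no tie to 1 chromosome, is argued against by this 99%, and a trend with gene length by a median of 0.55 after a line on length was taken out. An extra copy of chromosome 19 may be present, as a hypothesis: the median of 0.54 lay near the 0.58 that 3 copies in place of 2 would give, and the medians of the other chromosomes lay from -0.01 to 0.03. The median was 0.49 over all 435 tested genes and 0.54 over 153 genes of a stricter minimum, -0.01 in the library with the same title stem (BPA replicate 14), 0.08 in BPS replicate 1 and -0.06 to 0.04 in the other 38. No explanation by treatment was tested, since a single library holds the pattern.

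With library quality weights, 91 genes were called between BPS and CTL, 80 higher and 11 lower, among them Rgl3 (log2 0.36, SE 0.07, adjusted p = 0.0216), Preb (0.19, SE 0.03, 0.0216), Snai1 (0.29, SE 0.06, 0.0269) and the Notch target Hey1 (0.38, SE 0.07, 0.0266). Chance cannot be excluded: 21 of 100 splits of the libraries within sex called as many, and the highest other split called 5201. In simulated data the weights called a median of 36.5 and up to 4261 unchanged genes, with at least 1 in 18 of 20 simulations. With whole libraries shuffled they called up to 7577 genes, and at most 1 with each gene shuffled apart (100 shuffles each). Such counts may reflect a structure of the samples, in the sense of variation shared by many genes. Shuffling each gene apart also evens out the spread between libraries, which the weights fit, so these shuffles cannot separate the causes. BPS replicate 1 was weighted at 0.0536 and the other libraries at 0.209 to 2.94, and 103 genes were called without it. The code-titled libraries, which hold no CTL, might contribute: with weights and number-titled libraries alone, 10 of the 16 BPS and all 10 CTL, 0 genes were called (smallest adjusted p = 0.112, 2872 at an unadjusted p under 0.05). The 91 genes then had a median change of 0.26 (median SE 0.072) against 0.3 (0.069) with all libraries, so the calls ended with a smaller change, a larger SE and fewer libraries. Without weights the median change was 0.17 with number-titled libraries alone against 0.24 with all. In both cases 91 of 91 genes kept their direction, but the same libraries had helped to pick them, so this gives no independent support. Without weights, code-titled libraries stood 0.16 above number-titled ones within BPS and 0.17 within BPA. An effect of BPS stays open beside these.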

How the results depend on the processing

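The fits with voom, normal scores, the slope on gene length, the first 8 libraries, the 4 doubted libraries left out, combined weights, code-titled libraries alone and, for lists, leaving out treated libraries were chosen only after the results were seen. Changes of a count are given without a tested reason: the cause was not tested, except that fewer libraries were used where some were left out and that a fold minimum removes calls by construction. Depth set a floor of 3 reads, at most 0.07745 TPM on 1 kb.

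Against a count of 0 genes between BPS and CTL, 3 (1 higher, 2 lower) were called with median scaling, 3 (0 and 3) with quantile normalization, 91 (80 and 11) with quality weights, 103 (91 and 12) with weights and without BPS replicate 1, 28 (15 and 13) with the slope as a covariate, and 31 (17 and 14) with the first 8 libraries and the slope as covariates. With weights and code titles left out, the 91 between BPS and CTL became 0 (smallest adjusted p = 0.112), while 21 (20 and 1) were called between BPA and BPS in males. The other treatment and interaction counts stayed at 0 in the alternatives run. Without 1 library at a time all treatment and interaction counts were 0 to 0.

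Against 11 genes (5 higher, 6 lower) between the sexes, the count was 26 (8 and 18) with median scaling, 20 (6 and 14) with quantile normalization, 6 (5 and 1) with code titles left out, 0 with code-titled libraries alone, 40 (10 and 30) with weights, 38 (10 and 28) with weights and without BPS replicate 1, 37 (12 and 25) with weights and code titles left out, 67 (8 and 59) with the title stem as a random block, 4 (4 and 0) at 1.5-fold or more, 7 (4 and 3) with normal scores, 22 (7 and 15) without the 4 doubted libraries and 30 (8 and 22) with the slope. With the first 8 libraries as a covariate it was 21 (6 and 15), with the kind of title added 24 (6 and 18), with the slope added 26 (6 and 20), with both 35 (10 and 25), and without these 8 libraries 21 (6 and 15). Leaving out 1 library gave 11 to 23.

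Lists called were 10 between BPA and CTL, with 13 (5 higher, 8 lower) under median scaling, 6 under the slope and 1 with the estimated correlation (7 to 15 without 1 library and 11 without the 4 doubted ones). They were 6 between BPS and CTL, with 3 (3 higher, 0 lower) under median scaling, 3 with code titles left out and 0 with the estimated correlation (0 to 10 and 8). They were 9 between BPA and BPS, with 2 without a filter, 3 with 3 tissue scores as covariates and 0 with the estimated correlation (2 to 13 and 7). The correlation of the BPA and BPS effects, 0.711, was 0.456 with code titles left out and 0.618 to 0.8 without 1 library.

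Directions turned, in log2, for Ddx3x between the sexes with tissue scores (0.008), in code-titled libraries alone (0.046) and without BPA replicate 2 or CTL replicate 1 (0.001 and 0.017, from -0.146 to 0.017 over all single libraries). With weights they turned for Klrg1 (0.072) and Hoxa10 (0.119) between BPS and CTL, and for Rps6ka6 (-0.021), Cryab (0.054) and Hif1a (-0.013) between BPA and BPS. Hoxa10 turned to 0.048 without the 4 doubted libraries, and in code-titled libraries alone Gzmc (0.001) and Th (0.084) between BPA and BPS. Of lists, given by adjusted p, these turned between BPA and BPS: spongiotrophoblast (0.991) and decidua markers (0.74) with tissue scores, ribosomal proteins and oxidative phosphorylation without BPS replicate 1 (0.154 and 0.0916), without the 4 doubted libraries (0.271 and 0.282) and with the slope (0.771 and 0.673). Oxidative phosphorylation between BPA and CTL turned without CTL replicate 1 (0.741) and with the slope (0.699). Without 1 library these lists ranged from 4.82e-14 to 0.154 (ribosomal) and 1.93e-10 to 0.196 (oxidative phosphorylation) between BPA and BPS, and from 1.43e-09 to 0.741 between BPA and CTL. Of the other values of named genes under alternatives, leave-one-out apart, 1561 kept direction and side of the threshold, 27 gained a call and 22 lost one, and of list values 162 kept theirs and 81 lost the call.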

Other observations

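The splits of the samples, the shuffled data, the relation of the 2 maternal scores and the Wdfy1 values were chosen only after the results were seen. Labyrinth trophoblast, the exchange layer of the placenta, was not called in any comparison (adjusted p = 0.344 for BPA against CTL, 0.0586 for BPS against CTL and 0.0518 for BPA against BPS). All 17 of its markers were higher under BPA than in CTL (mean log2 0.11) and 15 of 17 under BPS (0.15), with Tfeb at log2 0.27 and Ly6e at 0.23 under BPS (0.13 and 0.16 in number-titled libraries alone), each above the CTL median in 13 of 16 libraries. Cell cycle genes were higher in 13 of 13 under BPA (mean log2 0.19, adjusted p = 0.0764) and 12 of 13 under BPS (0.14, 0.34), and stood at adjusted p = 0.753 between the compounds. Imprinted genes, many of which set placental growth, were higher in 21 of 23 under BPA (mean log2 0.13, adjusted p = 0.358) and 17 of 23 under BPS (0.11, 0.249), at 0.351 between the compounds. The median of all 12738 tested genes was also higher, at log2 0.064 under BPA and 0.035 under BPS against CTL. Members also moved together, with an estimated correlation of 0.678 for labyrinth, 0.887 for cell cycle and 0.435 for imprinted genes. These counts of higher members therefore do not by themselves show a change specific to a list. Igf2, the imprinted growth factor and picked here by name, stood at 1329 ± 370 TPM in CTL, 1394 ± 309 in BPA and 1363 ± 286 in BPS. In BPS against CTL the decidua markers, at adjusted p = 0.0987, had a mean of -0.148, with Prl8a2 at log2 -0.62 (above the CTL median in 6 of 16 BPS libraries) and Hoxa10 at -0.25 (in 11 of 16). CTL replicate 8 was the highest CTL library for both, and without it the mean was 0.044, Prl8a2 stood at -0.32 and Hoxa10 at -0.01.

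The remaining lists were not called (adjusted p in the order BPA against CTL, BPS against CTL, BPA against BPS): fetal endothelium 0.933, 0.328 and 0.0671, stroma and pericytes 0.234, 0.262 and 0.659, macrophages 0.963, 0.955 and 0.803, yolk sac endoderm 0.284, 0.955 and 0.296, stratified epithelium 0.0764, 0.222 and 0.889, striated muscle 0.447, 0.328 and 0.491, xenobiotic metabolism 0.791, 0.906 and 0.925, endoplasmic reticulum and heat stress 0.823, 0.428 and 0.259, and immediate early genes 0.485, 0.97 and 0.5. Lists called in other comparisons stood at 0.279 for progenitors, 0.323 for erythroid markers, 0.1 for smooth muscle, 0.0764 for serotonin and dopamine genes, 0.0764 for nutrient transporters and 0.143 for hypoxia genes in BPA against CTL. In BPS against CTL they stood at 0.921 for spongiotrophoblast, 0.691 for progenitors, 0.474 for erythroid markers, 0.0987 for neutrophils, 0.955 for serotonin and dopamine genes, 0.906 for hypoxia, 0.112 for DNA methylation, 0.262 for interferon genes and 0.791 for oxidative phosphorylation. In BPA against BPS they stood at 0.135 for giant cells, 0.0671 for neutrophils, 0.0671 for smooth muscle, 0.732 for steroid hormone genes, 0.259 for nutrient transporters, 0.803 for DNA methylation and 0.138 for interferon genes. Neuronal markers, with 4 tested members, were not tested, and had 4, 4 and 0 members higher. The Y-linked list had 4 tested members, called between the sexes, and the X list 4, not among the 11 genes called.

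Camera ranks a list against the other genes, so its direction can oppose the sign of the list's own change. It was down while mean and median were above 0 for these lists, none of them called (mean and median log2). In BPA against CTL they were progenitors (0.02 and 0.041), fetal endothelium (0.074 and 0.076), yolk sac endoderm (0.089 and 0.101), nuclear receptors (0.03 and 0.055), estrogen responsive genes (0.072 and 0.095) and immediate early genes (0.019 and 0.063). In BPS against CTL they were spongiotrophoblast (0.03 and 0.05), macrophages (0.018 and 0.076), yolk sac endoderm (0.163 and 0.138), immediate early genes (0.02 and 0.049) and oxidative phosphorylation (0.026 and 0.027). Between the compounds they were stroma and pericytes (0.023 and 0.045), xenobiotic metabolism (0.027 and 0.011), imprinted genes (0.02 and 0.016) and DNA methylation (0.017 and 0.033).

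Mean and median differed in sign for other lists. With camera down, these were serotonin and dopamine genes (-0.01 and 0.013), hypoxia genes (-0.009 and 0.037) and the called oxidative phosphorylation subunits (0.002 and -0.003) in BPA against CTL, and estrogen responsive genes (0.033 and -0.027) and immediate early genes (-0.001 and 0.024) between the compounds. With camera up, they were endoplasmic reticulum stress genes (0.058 and -0.007) in BPS against CTL and stratified epithelium (0.025 and -0.013) between the compounds.

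The decidua and natural killer scores followed each other over the 40 libraries (r = 0.67, permutation p = 2e-05, Spearman 0.69, permutation p = 1e-05, the smallest possible; adjusted p = 2e-05 over 2 relations, 0.63 without the 2 farthest libraries, 0.74 in number-titled and 0.54 in code-titled ones). Wdfy1, picked after its values were seen for a gap between 2 sets of libraries, lay at 4.13 to 4.62 on the log2(TPM + 1) scale in 15 libraries and at 4.88 to 5.32 in 25. The lower set held 4 CTL, 6 BPA and 5 BPS libraries, 8 of 10 code-titled and 7 of 30 number-titled ones, and 5 of 5 pairs with a shared title stem lay on 1 side.

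Each count was set against 100 splits of the same libraries, with the real grouping among them. The 11 genes between the sexes were matched by 3 of 100 splits, though the highest other split called 4907. That share is low, but a count cannot exclude chance for the called genes that are not Y-linked. Chance cannot be excluded for the gene lists called: 58 of 100 splits called as many as the 10 between BPA and CTL (highest other 20), 86 as many as the 6 between BPS and CTL (20) and 69 as many as the 9 between BPA and BPS (16). Counts of 0 genes were matched by 100 of 100 splits by definition. For these, the highest other split called 0 between BPA and CTL, 0 in females and 46 in males, and 0 between BPS and CTL, 4552 in females and 0 in males. Between BPA and BPS it called 1004, with 2386 in females and 0 in males, and for the interactions 0 under BPA and 2466 under BPS. Splits with such counts may reflect a structure of the samples, in the sense of variation shared by many genes. In unchanged data made by shuffling whole libraries, which keeps that variation, limma called up to 7583 genes, in the interaction under BPA, where no other split called any. It called up to 4354 for BPS against CTL in females, 2068 for BPA against BPS in females and 2550 for the interaction under BPS. With each gene shuffled apart, which removes the shared variation and also evens out the spread between libraries, limma called at most 2 in any comparison (100 shuffles each). Between the sexes the shuffles gave at most 11 and 0, far under the 4907, and between BPA and BPS at most 0 and 1, under the 1004. Both split counts are left without an explanation. The 944 genes at an unadjusted p under 0.05 between BPS and CTL were matched by 24 of 100 splits (highest other 4004).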
